A study of Caenorhabditis elegans with 7 samples.

How the data were processed

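The series is a chromatin immunoprecipitation sequencing (ChIP-seq) experiment on young adult hermaphrodites of the nematode Caenorhabditis elegans. The strain, OP37, carries a transgene, wgIs37, in which PHA-4 is fused to the tags TY1, EGFP and 3xFLAG beside a rescuing copy of unc-119. PHA-4 is the worm's FoxA transcription factor and is required to form the pharynx. Per the labels' protocols, worms grown at 20 °C were crosslinked with formaldehyde, chromatin was sheared by sonication, and PHA-4::GFP was collected with a goat antibody against GFP. A part of each lysate was kept as input DNA, the unselected control. The labels name 7 sequenced samples: 2 ChIP samples of biological replicate 1, 2 ChIP samples of biological replicate 2 and 3 input samples of replicate 2. An input sample of replicate 1 was not analysed here, and which input was used to call the replicate 1 and combined peaks is not given in the sources used here.

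The authors deposited 3 peak lists: 1 for each replicate and 1 called on the combined data, as the file names say. Per the file headers, peaks were called with PeakSeq on the genome build WormBase WS190. PeakSeq scores ChIP reads in a region against input reads, so a wider region can reach a smaller q-value at equal occupancy. The value deposited for each peak is a q-value, a p-value adjusted for multiple testing, and it stands in the file together with the first and last base of the peak. Every deposited q-value lay under 0.01. The PeakSeq version, the aligner, the read filters and the way in which the 2 samples of a replicate were merged are not given in the sources used here. The lists hold no read counts, peak heights or summits, so the depth of each sample is unknown, and the input samples enter only through the authors' q-values. A list from more deeply sequenced samples holds more and smaller q-values at equal occupancy. For this reason q-values were used to rank and compare peaks within a list, and between the replicates only in a correlation across peaks.

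From the lists, the width of each peak, its rank by q-value (ties by width, then position) and its overlap with peaks of the other lists were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0. Peaks were called shared when they had at least 1 bp in common. The number of shared peaks was tested with a one-sided permutation test in which the peaks of 1 list were rotated along each chromosome by a random distance, 100000 times. The strength (−log10 q) of shared and other replicate 2 peaks was compared by the difference of medians in a two-sided permutation test with 100000 resamples. The smallest p that these permutations can give is 1e-05. The number of peaks per chromosome was compared with the chromosome's share of the genome by two-sided exact binomial tests with Benjamini-Hochberg adjustment over the 6 nuclear chromosomes of each list. The length of a chromosome was taken as the distance from the first to the last peak over the 3 lists, in place of the assembled length chosen before the data were examined, because WS190 chromosome lengths were not in the sources used here. The recovery of combined peaks in a replicate list was compared between chromosomes by permuting chromosome labels within 10 classes of combined rank. Intervals are 95% exact (Clopper-Pearson) binomial intervals over peaks. They cover counting error only. Peaks are not replicates, and with 2 replicate lists the variation between worm cultures has no error estimate of its own. The combined list was made from the same samples as the replicate lists and is not independent of them.

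The overlap, median and recovery tests were tested on simulated data. Of 40 simulated unrelated lists with the sizes of the replicate 1 and replicate 2 lists, 0 passed p = 0.05 in the permutation test. All 209 of 209 planted overlaps were counted, which checks only the counting, since each was placed on a replicate 2 peak. The recovery test called 2 of 100 simulated combined lists without a loss on chromosome I and 100 of 100 in which the chance of recovery there was reduced to 50%. The median test called 3 of 50 simulations without a difference and 49 of 50 with a difference of 0.5 in −log10 q.

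Tests, alternatives and the rule for named regions were fixed before the data were examined, except where stated. The binomial tests of chromosomes other than X and Fisher's exact test of chromosome shares were not among the tests fixed beforehand. Nor were the width test and the recovery test, so the results on chromosomes I, III and V were not planned. The regions named are the 15 combined peaks with the smallest q-values, the 5 strongest peaks of each replicate list that the other replicate list lacks, and regions singled out in the closing section, which were chosen after their values were seen. The parts of that rule that call for gene names were not applied. The alternatives were an overlap of at least 50% of the shorter peak, midpoints within 200 bp, the stronger 50% of each list, equal list lengths, the middle 50% of widths and either replicate list in place of the combined list. Added after the data were seen were rotations of only 20 to 200 kb, the exclusion of chromosome I and the exclusion of peaks under 50 bp. Peaks were not assigned to genes. The gene table at hand is on the assembly WBcel235, and coordinates of different builds were not mixed. The tests planned on gene 5' ends, on gene lists and on the FoxA motif were therefore not run, and the sequence and annotation of WS190 were not used here. All columns of values were used, and 0 columns of other samples were left out. Plots were drawn with matplotlib 3.10.9.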

Results

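To locate the regions bound by PHA-4 in young adults, PHA-4::GFP was immunoprecipitated from 2 biological replicates of strain OP37, with 2 sequenced ChIP samples in each, and 3 input samples were sequenced for replicate 2. The replicate 1 list held 418 peaks over 0.399 Mb, the replicate 2 list 1834 peaks over 1.58 Mb and the combined list 2436 peaks over 2.14 Mb. Median widths were 619 bp, 489 bp and 498.5 bp. Read depth is unknown, and a difference in list length cannot be separated from a difference in depth or in input. Most regions were narrow, but 38 combined peaks were wider than 5000 bp. At the other end, 34 combined peaks and 13 replicate 2 peaks were narrower than 50 bp, and the replicate 1 list had 0 such peaks.

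The 15 strongest PHA-4::GFP regions of the combined list, which pools both replicates, were broad, were found in both replicate lists, and lay mainly on chromosome V. Of the 15 combined peaks with the smallest q-values, 8 lay on chromosome V, 2 each on I, II and X, and 1 on IV. All 15 overlapped a peak in both replicate lists, and their widths ran from 1860 to 20049 bp, with 14 of the 15 wider than 2000 bp. A ranking by q-value can itself favour wide regions. All positions are given in WormBase WS190 coordinates.

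The first in rank was V, 723560 to 728365 (4806 bp, combined q = 2.52e-193). It was also the strongest peak of replicate 2 (q = 9.61e-178) and the second of replicate 1 (q = 2.42e-36). The next was V, 20740549 to 20760597, with a combined q of 4.81e-143. At 20049 bp it was the widest region, and the next widest combined peak, V 6220741 to 6230123, measured 9383 bp and ranked 15. The gene pha-4, of which the transgene adds copies, lies toward this end of chromosome V. Replicate 2 called nearly the same interval as a single peak of 19897 bp (q = 5.63e-85). Replicate 1 divided it into 5 peaks that covered 68.2% of it, the strongest of which ran from 20745614 to 20752590 (6977 bp, q = 3.71e-16).

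**Figure D1:**
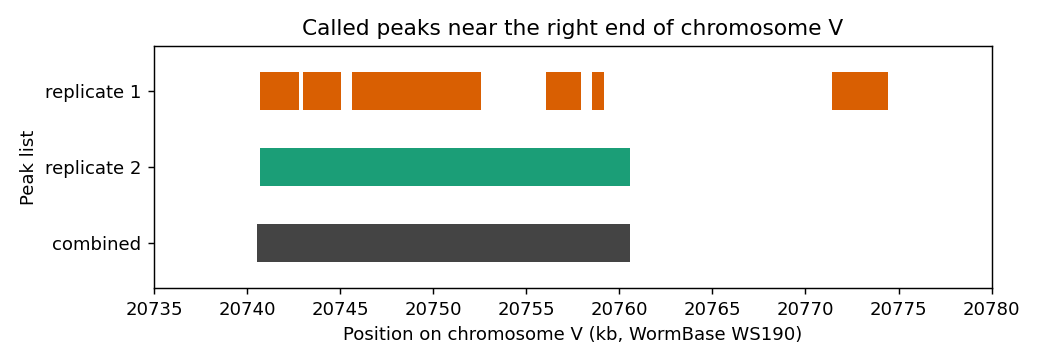
Called peaks near the right end of chromosome V, with the position in kb (WormBase WS190) on the x axis and a row for each peak list; each bar spans a peak from its first to its last base. Replicate 2 and the combined list have a single peak of 19897 and 20049 bp, where replicate 1 has 5 peaks, and the replicate 1 peak from 20771413 to 20774423 has no partner in the other lists.

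On the X chromosome, the leading regions were 16929344 to 16932030 (2687 bp, combined q = 1.47e-118) and 1503355 to 1505214 (1860 bp, q = 7.97e-116). They were the narrowest combined peaks down to rank 7. Replicate 1 called them at ranks 7 and 10 and replicate 2 at ranks 3 and 2. The chromosome IV region 4467945 to 4474494 spanned 6550 bp (q = 7.33e-112), and replicate 1 held 3 separate peaks inside it. On chromosome I, 7489451 to 7493461 (q = 4.82e-111) and 7656486 to 7661611 (q = 2.35e-104) followed at ranks 6 and 7. In replicate 2 these chromosome I regions ranked 4 and 7, and in replicate 1 they ranked 21 and 49.

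The remaining regions of this set were V 11887657 to 11890019, V 13907416 to 13910950, II 6887855 to 6892732, V 7431505 to 7435424, II 10541871 to 10549751, V 9074224 to 9077304, V 18558264 to 18560525 and V 6220741 to 6230123. Their combined q-values ran from 6.12e-102 to 3.92e-61. V 11887657 to 11890019 stood out in replicate 1, where it ranked 3 with q = 8.85e-25, and it ranked 8 in replicate 2. V 18558264 to 18560525 had the lowest replicate 1 rank of the 15: a peak of 474 bp was called there at rank 137 of 418 (q = 7.44e-05). Replicate 2 called 2260 bp at rank 13 of 1834, and ranks in lists of unlike length do not measure a change.

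The replicates were compared to see which regions were found in both. Most replicate 1 regions recurred in replicate 2, while most replicate 2 regions were missing from the shorter replicate 1 list. Of the 418 replicate 1 peaks, 345 (82.5%, 95% interval 78.6 to 86.1) overlapped a replicate 2 peak, against a mean of 13.7 and a maximum of 93 when replicate 1 peaks were rotated along their chromosomes (one-sided permutation p = 1e-05, the smallest possible). In the other direction, 321 of the 1834 replicate 2 peaks (17.5%, 15.8 to 19.3) overlapped a replicate 1 peak, against 13.8 by rotation (one-sided permutation p = 1e-05). When replicate 2 was limited to its 418 strongest peaks, 213 replicate 1 peaks (50.96%) were shared, against 4.76 by rotation. Demanding midpoints within 200 bp left 205 shared replicate 1 peaks (49.0%).

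Shared regions were the stronger and wider ones, although strength by q-value and width are not independent measures. Replicate 2 peaks that replicate 1 also held had a median −log10 q of 6.07, and the others 3.05, a difference of 3.03 (two-sided permutation p = 1e-05). Their median width was 882 bp against 451 bp (two-sided permutation p = 1e-05). Of the 100 strongest replicate 2 peaks 71 were found in replicate 1, and of those ranked 801 to 1834 only 7.16% were. Of the 100 strongest replicate 1 peaks, 98 were found in replicate 2, and of those ranked 201 to 418, 157 of 218 (72.0%) were. Over the 345 replicate 1 peaks with a partner, strength in the replicates was related with a Spearman rho of 0.44 (95% bootstrap interval 0.35 to 0.52) and a Pearson r of 0.56 on −log10 q, and width with a rho of 0.76. These are relations across peaks, which are not independent replicates.

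The strongest replicate 2 regions that replicate 1 lacked were V 9095065 to 9097678 (rank 20, q = 8.96e-37), II 14598295 to 14601744 (rank 30), V 20157752 to 20159563 (rank 33), III 5550617 to 5552616 (rank 36) and III 10716877 to 10720610 (rank 41, q = 2.27e-25). All 5 were also in the combined list, at ranks 36 to 74. In replicate 1 the strongest peak of the whole list had no partner. It lay at the right end of chromosome I, which carries the tandem ribosomal RNA genes, at 15064033 to 15067630 (3598 bp, q = 1.63e-113), where neither replicate 2 nor the combined list held a peak. The next, V 20771413 to 20774423 (rank 35, q = 3.58e-10), was also in neither list. The other 3, X 3825797 to 3826637, IV 3050197 to 3050988 and IV 10503661 to 10504317, ranked 113, 115 and 134 and were in the combined list at ranks 644, 729 and 907.

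The combined list was divided by its support in the replicates. Both replicate lists held 314 of the 2436 combined peaks (12.9%, 95% interval 11.6 to 14.3), replicate 2 alone held 1365 (56.0%), replicate 1 alone held 60 (2.46%) and neither held 697 (28.6%). Median −log10 q fell from 11.6 for peaks in both lists to 3.83 for those in replicate 2 alone and 2.42 for those in neither. The strongest combined peak that replicate 2 lacked was at rank 450, and replicate 2 held every one above it. Replicate 1 held 83 of the first 100 combined peaks, 63 of the next 100, and 9 of the 836 ranked from 1601 on. Of the replicate lists, 408 of 418 replicate 1 peaks (97.6%) and 1711 of 1834 replicate 2 peaks (93.3%) were in the combined list.

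**Figure D2:**
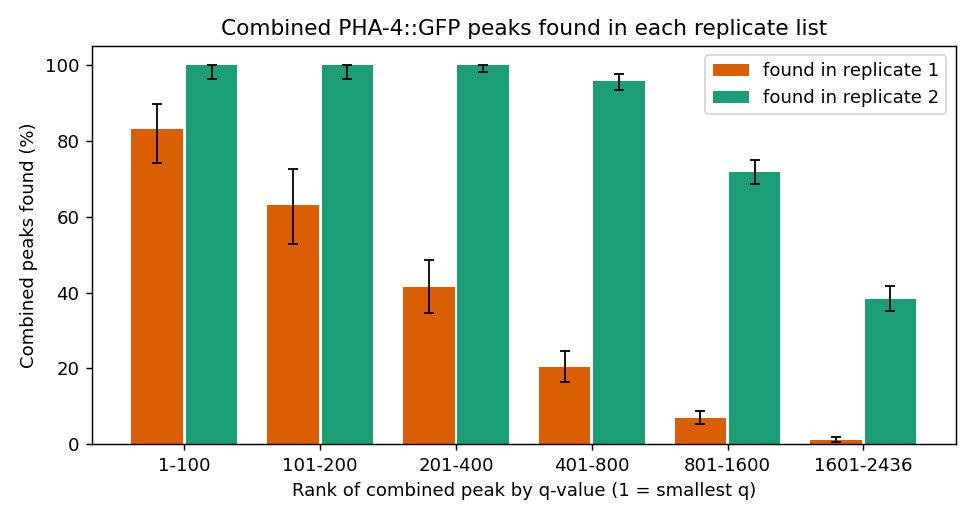
Percentage of combined peaks found in each replicate list (y axis) by the rank of the combined peak (x axis, 1 is the smallest q-value), with 95% exact binomial intervals as error bars. Recovery in replicate 1 falls from 83% of ranks 1 to 100 to 1.08% of ranks 1601 to 2436, and in replicate 2 from 100% to 38.4%.

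Peaks were not spread over the chromosomes in proportion to length. Chromosome V had the fewest combined peaks for its length, 348 or 16.7 per Mb, which is 14.3% of peaks on 20.95% of the covered length (exact binomial test, adjusted p = 1.91e-16), although it held 8 of the 15 strongest regions. Chromosome III had the most, 406 or 29.9 per Mb (16.7% of peaks on 13.6% of the length, exact binomial test, adjusted p = 7.13e-05). Combined peaks on I, II, IV and X numbered 26.2, 25.9, 25.4 and 25.96 per Mb, and their shares did not pass the test. The low share of V held in replicate 2 (14.8%, exact binomial test, adjusted p = 1.01e-10) and was not past the threshold in replicate 1 (16.7%, exact binomial test, adjusted p = 0.0529). The share of III was 17.7% in replicate 2 (adjusted p = 2.75e-06) and 17.9% in replicate 1 (adjusted p = 0.025), both by exact binomial test. Both replicate lists were short of peaks on chromosome I, replicate 1 the more so, which raises their shares on the other chromosomes. The shares of III and V were not retested without chromosome I, so their calls in replicate 1 may depend on it. The exact binomial tests count each peak as independent, which neighbouring peaks are not. Their p-values may therefore be too small, and no rotation or thinning was applied to chromosome shares.

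**Figure D3:**
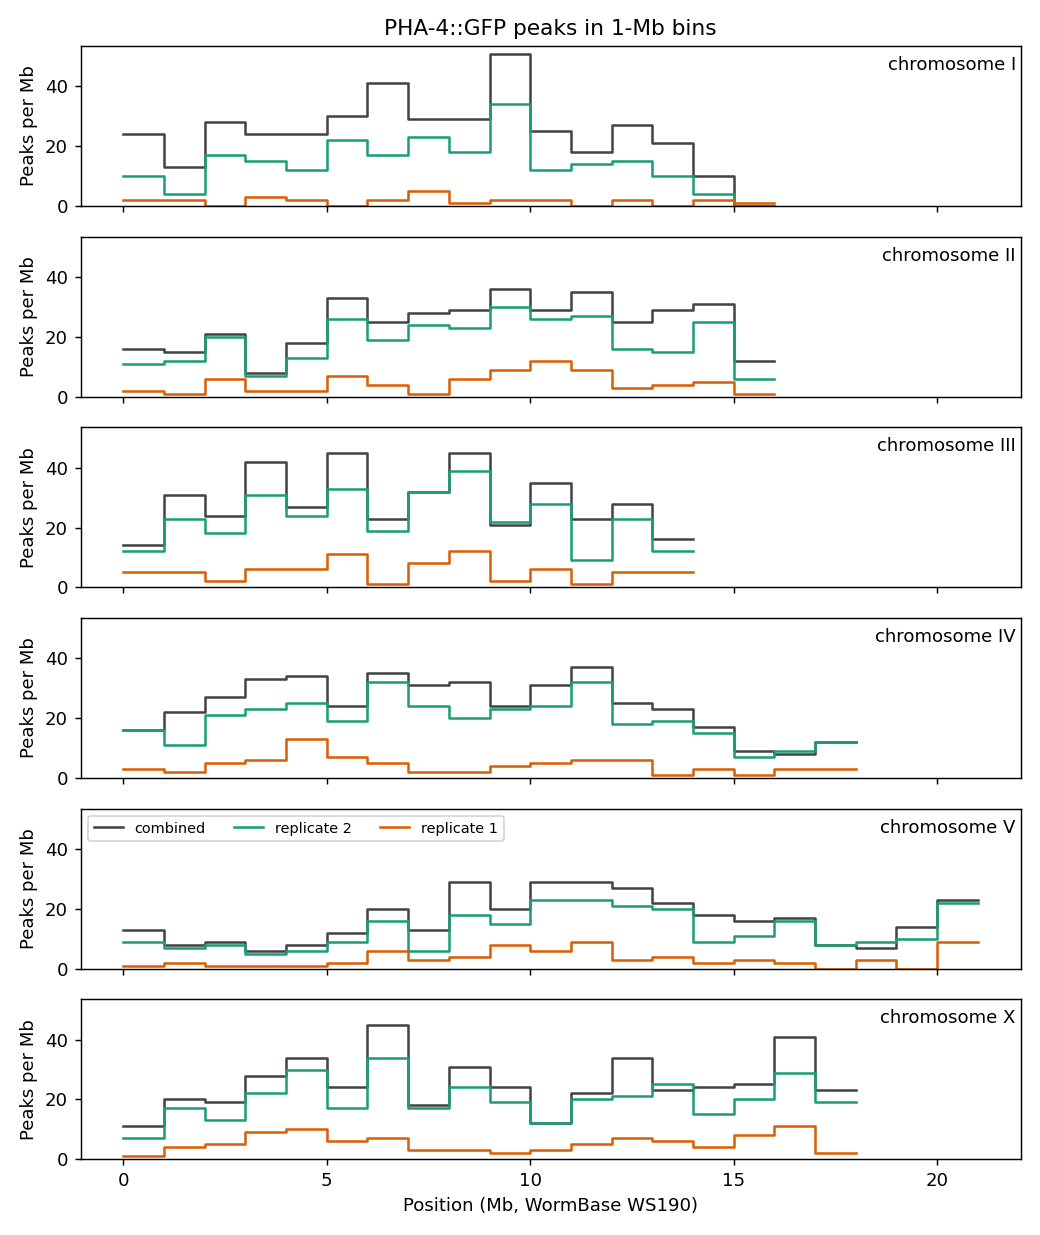
Number of peaks in each 1-Mb bin (y axis) along the 6 chromosomes (x axis, Mb in WormBase WS190), for the replicate 1, replicate 2 and combined lists; the last bin of each chromosome is not a full Mb. On chromosome V the combined list has 6 peaks in the bin from 3 to 4 Mb and 29 in the bin from 8 to 9 Mb, and on chromosome I replicate 1 has at most 5 peaks in any bin.

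The X chromosome was compared with the autosomes. X held 458 combined peaks, 18.8% (95% interval 17.3 to 20.4) where its length gave 17.7% (two-sided exact binomial p = 0.168, adjusted p = 0.252 over 6 chromosomes). The share was higher in replicate 1, with 96 of 418 peaks or 23.0% (p = 0.00701, adjusted p = 0.021), and in replicate 2, with 361 of 1834 or 19.7% (p = 0.0299, adjusted p = 0.0449), both by exact binomial test. Without chromosome I, where both replicate lists were short of peaks, the share on X was 24.5% in replicate 1 and 22.5% in replicate 2 against 20.9% by length, and neither passed the test (exact binomial p = 0.0819 and 0.125). These tests also count neighbouring peaks as independent, so the calls near the threshold are uncertain.

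Chromosome I differed most between the lists. It held 26 replicate 1 peaks (6.22%), 227 replicate 2 peaks (12.4%) and 394 combined peaks (16.17%) on 15.1% of the length. Its share was lower in replicate 1 than in replicate 2 (Fisher's exact test, odds ratio 0.47, adjusted p = 0.00123 over 6 chromosomes), and the shares of the other 5 chromosomes did not pass that test (Fisher's exact test, adjusted p from 0.415 to 0.943). Fisher's test assumes independent counts, but 345 of the 418 replicate 1 peaks overlapped a replicate 2 peak. With 1 list per replicate, its p does not measure variation between worm cultures. Replicate 1 held 22 of the 394 combined peaks of chromosome I (5.58%, 3.53 to 8.33) and 17.2% of those elsewhere, and replicate 2 held 52.03% against 72.2%. Within the 10 classes of combined rank, 52.9 peaks would have been found in replicate 1 and 260.4 in replicate 2, where 205 were found (two-sided permutation tests, adjusted p = 6e-05 for each over 12 tests). Ranks still differ inside a class, so differences of strength were reduced and not removed. On X, more were found than expected within these classes (88 against 71.7 in replicate 1, adjusted p = 0.0226, and 335 against 316.4 in replicate 2, adjusted p = 0.0348, permutation tests). With chromosome I left out, none of the other 5 chromosomes passed in either replicate (permutation tests, lowest adjusted p = 0.593 over 10 tests).

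**Figure D4:**
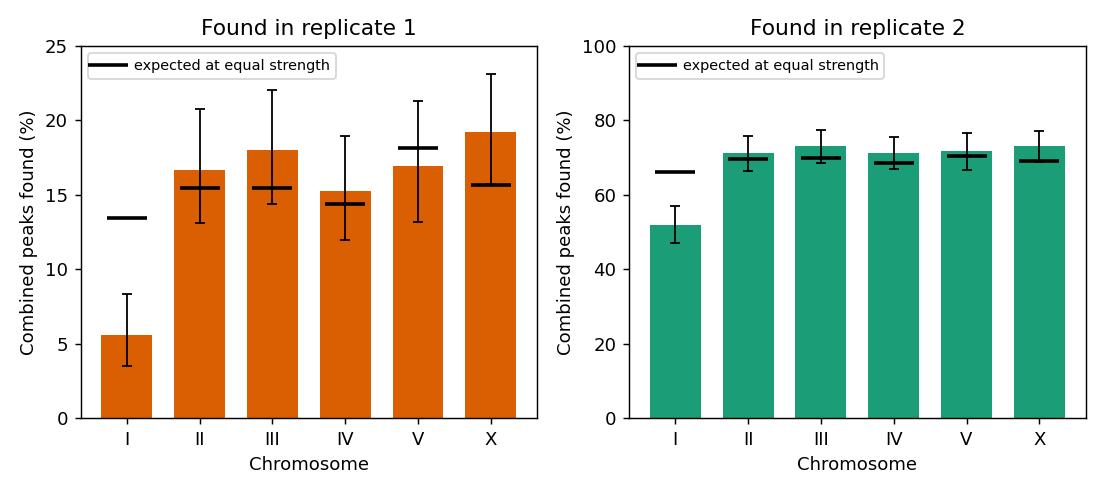
Percentage of the combined peaks of each chromosome (x axis) found in replicate 1 (left) and replicate 2 (right), on y axes with different ranges. Error bars are 95% exact binomial intervals. Black marks the percentage expected within 10 classes of combined rank, which the legend calls equal strength. Chromosome I lies below its mark in both, at 5.58% in replicate 1 and 52.03% in replicate 2.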

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

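The rotations of 20 to 200 kb and the exclusions of chromosome I and of peaks under 50 bp were chosen after the data were seen. Of 26 values recomputed under an alternative, 21 kept their direction and their side of the threshold, or stayed within the interval of the main value. All 10 alternatives for the overlap between replicates, in both directions, gave a permutation p of 1e-05, as did the 4 for the strength of shared peaks, where the difference of medians was 1.89 within the middle 50% of widths. Rotations of only 20 to 200 kb gave a mean of 13.9 chance overlaps and a maximum of 33, against 345 observed. The share of combined peaks held by both replicates was 7.39% when midpoints had to lie within 200 bp, by construction a stricter match for wide peaks, and 14.5% without chromosome I. The share of peaks on X, which did not pass the test in the combined list, passed it in either replicate list alone (19.7% without replicate 1 and 23.0% without replicate 2) and among combined peaks held by both replicates (23.9%, exact binomial p = 0.00609). In the replicate lists that call ended when chromosome I was left out: the excess over the share by length went from 5.24 to 3.6 percentage points in replicate 1 and from 1.96 to 1.58 in replicate 2, and fewer peaks were tested (392 and 1607). The combined peaks held by both replicates were not retested without chromosome I. Only 17 of these 314 peaks (5.41%) lay on it, against 15.1% of the length, which raises the share on X here too. Off chromosome I, X held 75 of 297 such peaks, so the call at p = 0.00609 (exact binomial test) may depend on chromosome I. Variants with gene 5' ends, gene lists, the motif or the number of genes per chromosome were not run, since no annotation or sequence of WS190 was used. Unknown depth limits every comparison of list lengths: a region that replicate 1 lacks was not detected there, which does not show that it was unbound.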

Other observations

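The tests of weaker peaks, of repeat signal, of transgene copies and of a site in both replicates were chosen after the result was seen, as were the thinned test of position, the rotation test of position and the regions named here. The rotation test was the last chosen, after the results of the other tests of position were known. The design has a single condition, so no biological explanation was tested for the patterns weighed on chromosomes I and V.

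Autosomal PHA-4::GFP peaks lay toward the middle of the chromosomes. With the covered length of each chromosome divided into 3 equal parts, the central part held 842 of 1978 autosomal combined peaks (42.6%, 95% interval 40.4 to 44.8) where even spacing gives 33.3% (exact binomial p = 1.32e-17), and in this list each of the 5 autosomes was above that value, from 38.4% on III to 48.6% on V. On X the share was 33.2% (exact binomial p = 1). The hypothesis that the pattern belongs to autosomes more than to X was tested by position along the chromosome. The difference was 9.38 percentage points in the combined list (Fisher's exact p = 0.000219), and the same direction held in replicate 1 (41.3% against 22.9%, although chromosome IV alone was at 29.9% there) and replicate 2 (44.0% against 34.6%). Neighbouring peaks are not independent, which these exact tests ignore. When all combined peaks of a chromosome were rotated together by a random distance, which keeps their spacing, the autosomal share passed (two-sided permutation p = 0.00042) and so did its difference from X (two-sided permutation p = 0.022, 95% range of the rotations -8.52 to 7.8 points). With only the strongest peak kept per 50 kb, 1208 of 2436 peaks were left. The autosomal share was then 38.3%, still above even spacing (exact binomial p = 0.00117). That of X was 31.8%, and the difference of 6.44 points did not pass (Fisher's exact p = 0.0776). Thinning limits dense stretches by construction and leaves fewer peaks, so it neither shows nor rules out the difference. In replicate 1 the share on X was itself below even spacing (exact binomial p = 0.0304), which adds to the difference there. The values go with a central excess on autosomes, as a hypothesis found and tested on the same peaks. The difference from X is less certain: it passed by rotation, the test chosen last, and did not pass after thinning. No test took the density of genes along the chromosomes into account, so a pattern particular to PHA-4 is not shown.

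The loss of chromosome I peaks from the replicate 1 list was seen in each part of the chromosome tested; the loss from replicate 2 was not tested by part. Weaker peaks on chromosome I cannot be told apart from other explanations. Replicate 1 found 0.416 of the number expected within 10 classes of combined rank, but combined q-values on chromosome I may not be comparable with those elsewhere. Of the 697 combined peaks in neither replicate list 26.4% lay on it, against 5.41% of the 314 in both. These shares restate the loss and do not by themselves show which list is shifted. Against its length, chromosome I was short in replicate 1 (6.22%) and in replicate 2 (12.4%) (exact binomial tests, adjusted p = 1.44e-07 and 0.00158). Its share was also lower in replicate 1 than in replicate 2 (Fisher's exact test, adjusted p = 0.00123). These comparisons do not use the combined list, so they argue against a shift of the combined list alone. Chromosome I held 16.17% of all combined peaks on 15.1% of the length. That share did not pass the exact binomial test (adjusted p = 0.252), so no excess by number was shown. Loss on one part of the chromosome is argued against: the left, central and right parts of equal length gave 0.494, 0.33 and 0.482 of the expected number, and in all 3 the number found lay below the 95% range of the permutations. These values go with a shift of the calling threshold over all of chromosome I in the replicate 1 list, alone or beside shifts in the other lists. A chromosome-wide scaling of ChIP against input would give this. Neither the scaling used nor the input against which replicate 1 was called is recorded in the lists. Repeat signal at the right end of chromosome I in replicate 1 alone cannot be told apart from this: replicate 2, with no peak there, also found only 0.787 of the expected number, but repeat reads under its calling threshold are not visible in a peak list.

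The region of 20049 bp on chromosome V was 2.14 times as wide as the widest other combined peak and 2.24 times as wide in replicate 2. In replicate 1 the widest peak inside it, of 6977 bp, was 1.54 times as wide as the widest elsewhere. The gene pha-4 itself lies toward this end of chromosome V, and the strain carries added copies of it in the transgene. Extra copies may widen and strengthen a call there, and several neighbouring sites joined by the caller would also give a wide peak. In replicate 1 the interval held 5 separate peaks, with gaps that left 68.2% covered. Joined sites would give this, but replicate 1 also held several peaks inside some other wide combined regions. The split therefore does not favour either explanation. The width ratio of 2.14 is what either explanation predicts, so added copies cannot be told apart from dense binding without the read depth of input DNA over the region.

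The strongest replicate 1 peak, I 15064033 to 15067630, lies at the chromosome end that carries the tandem ribosomal RNA genes. A binding site that both replicates hold stays open: 0 replicate 2 or combined peaks overlapped it, but the region was singled out because it had no partner, and a region without a peak is not shown to be unbound. The last other combined peak of chromosome I ended 114.9 kb to its left, and the last of replicate 2 ended 437.9 kb to its left. Whether repeat copies or the choice of input raised it was not tested, since the lists hold no reads, and whether the region was masked in the other lists is not recorded in them.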
